A study of Caenorhabditis elegans with 2 samples.

How the data were processed

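Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole young adult Caenorhabditis elegans at 63 hours, in a strain whose own ztf-25 gene carried a TY1, EGFP and 3xFLAG tag inserted by CRISPR. Per the labels, the precipitation used an antibody against GFP, the worms were synchronised by starvation at the first larval stage, and sonicated chromatin had a size range of 200 to 800 bp. The series held 2 samples, given by the labels as biological replicates 1 and 2 of 1 group. There was no second condition, so no comparison between conditions was made.

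The deposited files were 8 peak lists on the ce11 assembly, 4 thresholded and 4 ranked. Per the deposited README texts, each list was derived from alignments and a control file. Peaks were ranked by the irreproducible discovery rate (IDR), which scores how well a peak's rank repeats between 2 peak calls. The aligner, the peak caller and the treatment of duplicate reads are not given in the sources used here. Per the deposited README texts, the thresholded lists also derive from 1 further file whose content is not stated there.

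The signal value of a peak is the authors' own value from their peak calling, with a scale that is not stated. It was used to describe and rank peaks within a list, to compare groups of peaks within a list, and to correlate the 2 libraries. The score in the deposited thresholded lists is a transform of the IDR that ends at 1000, and its lowest value in the conservative list was 830. The deposited ranked lists give the −log10 of the global IDR for each peak. Matched against them, each peak of the conservative list had an IDR of 0.01 or lower. The ranked list of the 2 libraries set against each other also gives a signal value per library, in columns that do not say which replicate they hold, so those values are given without a replicate number. Its peaks at an IDR of 0.01 or lower numbered 1153, and 61 of them were not in the conservative list. These 2 columns were mapped to the group and to no sample.

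The files hold no read counts, so the depth of each library is unknown, and no interval that needs read counts is given. Exact binomial (Clopper-Pearson) 95% intervals are over peaks or genes, and cover the counting of these items only.

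The conservative list, which rests on both replicates, was the main peak set. Positions are 1-based. Genes came from the Ensembl release 115 annotation of WBcel235, which is the same assembly as ce11, and sequence and transfer RNA isotypes from the RefSeq files of that assembly. Only the 6 nuclear chromosomes were used. A promoter window ran from 1000 bp upstream to 500 bp downstream of any annotated 5′ end of a protein-coding transcript, and a gene was called bound when a summit lay in one of its windows. The replicate overlap, the promoter share and the noncoding gene classes were each set against 1000 random placements on the same chromosomes, whose smallest possible p is 0.000999 one-sided and 0.002 two-sided. Chromosome shares were tested with a two-sided exact binomial test. Signal differences and Spearman's rho were tested with 100000 permutations, whose smallest possible p is 1e-05. Annotation classes (exon, intron, UTR, intergenic) used 200 placements, with a smallest two-sided p of 0.00995. Gene lists were tested with a two-sided Fisher's exact test against the 10896 protein-coding genes that have a symbol other than their sequence name. All 35 lists had at least 5 members. Words of 7 bases, both strands merged, were counted in windows of 50 bp to either side of each summit and compared by Fisher's exact test with windows of the same width centred 500 bp to either side. Benjamini-Hochberg adjustment was applied over the 6 chromosomes, the 35 lists, the 9 noncoding classes or all 8192 words, and an adjusted p under 0.05 was a call.

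The peak set, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took ztf-25 itself, the gene with the nearest protein-coding 5′ end to each of the 12 conservative peaks with the highest signal, the 4 bound members with the highest signal in each called list, and the 1 bound member with the highest signal in each other list. Genes outside this rule appear only where they hold or neighbour such a peak, or are said to have been chosen otherwise. Alternatives fixed in advance were the combined list of the series, IDR limits of 0.01 and 0.1, each replicate's list alone, other windows, other overlaps, another background, nearest genes only, other word lengths and other control windows. An IDR limit of 0.001 and sets without peaks at tRNA genes or at small noncoding RNA genes were added after the data were seen. The small noncoding RNA genes here are transfer, small nucleolar, small nuclear and ribosomal RNA genes and tRNA pseudogenes. The annotation classes, the signal of tRNA gene peaks and the summit positions within noncoding RNA genes were also chosen after the data were examined.

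The tests were checked on 20 simulated sets of 1092 peaks. With planted effects, each of the 7 kinds of test made the call in 20 of 20 sets. The planted effect on signal by location was larger than the difference seen, and the simulated lists were random genes. The sets therefore do not measure power for small effects. With uniformly placed peaks, gene lists gave 0 calls in 700 tests, words 2 in 163840, the promoter share 2 in 20 and the tRNA class 1 in 20. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used on a single thread with fixed seeds.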

Results

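The binding of ZTF-25, a protein named as a zinc finger transcription factor, was mapped by ChIP-seq through an EGFP tag in whole young adult worms at 63 hours. The 2 samples were biological replicates of 1 group, and the question put to them was where in the genome the tagged protein was found. The conservative list of the series, which requires a peak to repeat between both libraries, held 1092 peaks that covered 294116 bp, or 0.293% of the nuclear genome. Their median width was 276 bp, and 34 of them were narrower. The combined list held 1368 peaks, the list of replicate 1 held 515 and that of replicate 2 held 295. The lists differ in which libraries or parts of libraries were set against each other, so their sizes and calls are not compared like for like. The depth of the libraries is unknown, since the files give no counts. No untagged or GFP-only sample was analysed here, so no background measured the same way stands beside these values.

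The tagged gene itself carried no peak. At ztf-25 (WBGene00012405, chromosome V, 17601820 to 17602970, plus strand, ce11), neither the conservative nor the combined list had a peak in the gene or within 1000 bp of it. The ranked comparison of the libraries had 5 peaks there, and the best of them, at 17602065 to 17602340, had an IDR of 0.285 and a signal of 41.99.

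The 2 libraries marked many of the same places. Of the 515 peaks of replicate 1, 213 overlapped a peak of replicate 2 by at least 1 bp, which is 41.4% (95% interval 37.1 to 45.7%). Random placements gave a mean of 0.148% and a maximum of 0.971%, for a one-sided permutation p of 0.000999, the smallest possible. Of the 295 peaks of replicate 2, 214 overlapped one of replicate 1, or 72.5%. Across the 104189 matched peaks of the ranked comparison, Spearman's rho between the libraries' signals was 0.271 (permutation p = 1e-05, the smallest possible), and over the 1092 conservative peaks, which were selected for ranks that repeat between these same libraries, it was 0.406. These correlations run across peaks, which are not independent replicates.

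The genes most often marked were those of transfer RNAs. Of 612 annotated tRNA genes, 314 (51.3%) had a summit within 200 bp, against a mean of 0.522% and a maximum of 1.96% in random placements. These genes accounted for 294 of the 1092 peaks, or 26.9%. Genes of small nucleolar RNAs (snoRNAs), which guide the modification of ribosomal RNA, followed with 59 of 346 genes (17.1%, random mean 0.583%), and small nuclear RNA (snRNA) genes with 15 of 129 (11.6%, random mean 0.537%). Among microRNA genes 8 of 261 had a summit nearby (3.07%, random mean 0.526%), through 5 peaks. The remaining annotated ncRNAs stood at 291 of 7764 (3.75%, random mean 0.605%), and 177 of the 256 peaks near them were also near a tRNA gene. The opposite held for piRNA genes, with 11 of 15363 (0.0716%, random mean 0.421%), and for pseudogenes, with 24 of 2128 (1.13%, random mean 1.95%). None of 20 annotated rRNA genes had a summit of the conservative list nearby and 3 of 194 lincRNA genes did, and both classes had a permutation adjusted p of 1. Of the 61 peaks at the same IDR limit that the list leaves out, 2 were near rRNA genes (chromosome V, 17122051 to 17122326 and 17129352 to 17129627). The other 7 classes were called by the permutation test, with adjusted p = 0.00514 for pseudogenes and 0.003 for the other 6. In the list of replicate 1 alone 198 tRNA genes (32.4%), 44 snoRNA genes (12.7%) and 11 snRNA genes (8.53%) had a summit nearby, and in that of replicate 2 alone 106 (17.3%), 31 (8.96%) and 5 (3.88%), all still called. The microRNA class fell to 4 genes (1.53%) in replicate 1 and 3 genes (1.15%) in replicate 2, and the remaining ncRNAs to 183 (2.36%) and 96 (1.24%), also still called. Pseudogenes were not called in the combined list (permutation adjusted p = 0.0591), in either replicate's list (0.239 and 0.658), at an IDR of 0.001 or without the peaks at tRNA genes. The piRNA class was not called when the summit had to lie within the gene, nor the microRNA class at an IDR of 0.001.

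**Figure D1:**
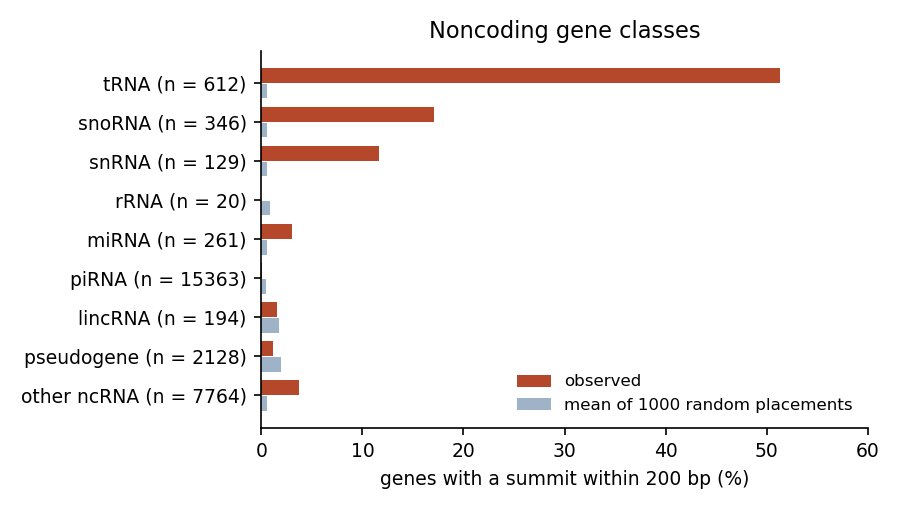
Percent of the annotated genes of each noncoding class with a conservative peak summit within 200 bp (red) and the mean percent over 1000 random placements of the peaks (blue), with the number of genes in each class. The tRNA bar reaches 51.3%, the snoRNA bar 17.1% and the snRNA bar 11.6%, all with random means under 1%.

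Summits lay inside tRNA genes and just upstream of snoRNA genes, in a description chosen after the data were examined. At tRNA genes the median summit was 23 bp downstream of the gene's 5′ end (quartiles 8 and 39 bp), and 236 of 294 summits (80.3%) were within the gene. At snoRNA genes 46 of 59 summits (78.0%) were upstream of the 5′ end, and 8 were within the gene. Signal at the 294 tRNA peaks had a median of 105.3, against 89.2 at the other 798 peaks (permutation p = 1e-05, the smallest possible, for a difference of 16.1). Many tRNA genes have identical copies, so that the authors' alignment may have split or dropped their reads. When a summit had to lie within the gene body, 236 tRNA genes and 8 snoRNA genes were marked.

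**Figure D2:**
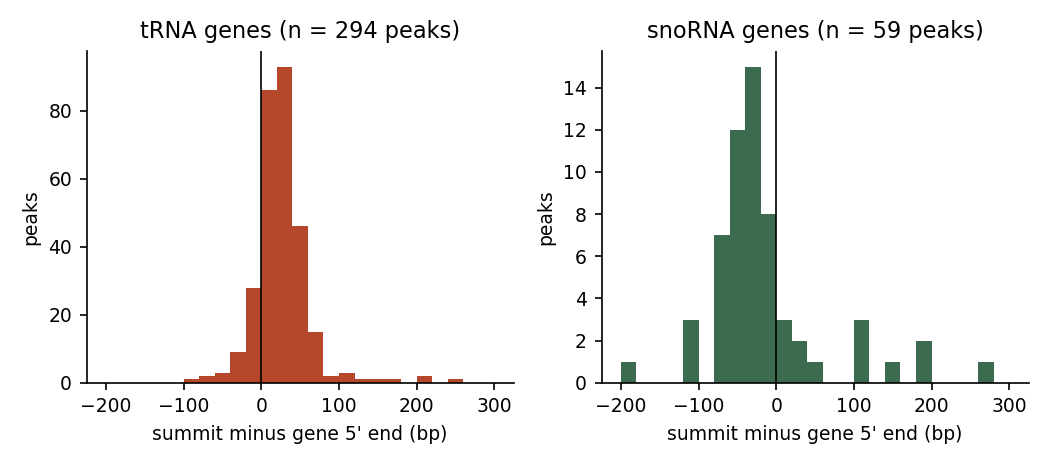
Position of conservative peak summits relative to the 5′ end of the closest tRNA gene (left, 294 peaks) or snoRNA gene (right, 59 peaks), in bp along the gene's strand, as the number of peaks in each 20 bp bin. Most tRNA summits fall just downstream of 0 and most snoRNA summits upstream of it.

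Peaks were found in promoter windows of protein-coding genes more often than random placements were. Of the 1092 summits, 466 lay in such a window, or 42.7% (95% interval 39.7 to 45.7%), against a random mean of 31.6% with an SD of 1.42 and a maximum of 35.8% (two-sided permutation p = 0.002, the smallest possible). Without the peaks at tRNA genes the share was 48.0%. By annotation, a division added after the data were examined, 52.3% of summits were intergenic (random mean 36.8%), 29.6% intronic (random mean 33.8%) and 11.8% in coding exons (random mean 24.3%), each with a permutation adjusted p of 0.0166 over 5 classes. The shares in 5′ UTRs (2.2%) and 3′ UTRs (4.12%) did not pass the permutation test, with adjusted p of 0.269 and 0.236.

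The strongest conservative peak lay 267 bp upstream of mog-4, which encodes a DEAH-box RNA helicase of germline sex determination, at chromosome II, 14561775 to 14561948. Its signal was 421.5 in the pooled libraries and 248 and 178 in the single ones. The second, at chromosome III, 5172607 to 5172772 (signal 356), lay 17 bp upstream of K10D2.5 and 658 bp upstream of prp-19. The third lay 633 bp upstream of rpa-2, a subunit of replication protein A, at chromosome I, 4769572 to 4769727 (signal 338). A peak in an intron of the peroxidasin gene pxn-1 (chromosome V, 8500483 to 8500649, signal 336) was within 200 bp of the snoRNA gene ZK994.7. Further intergenic peaks lay 508 bp upstream of K12H4.5 (signal 325), 57 bp upstream of tasp-1 (316) and 347 bp upstream of the ribosomal protein gene rpl-15 (297). The peak nearest to mtcu-2 (signal 323) was 463 bp upstream of it, within an intron of let-268. The peak at ints-8, an Integrator subunit gene (chromosome I, 13463890 to 13464043, signal 295), had its summit 2 bp into rpr-1, the RNase P RNA gene within its intron. The last 3 were intergenic peaks near C46C2.7 (signal 294) and K08F11.1 (291), and an intronic peak in cutl-18 (283) beside the snoRNA gene T03F7.8. All 12 were narrower than the full width, at 88 to 174 bp.

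Promoters of ribosomal protein, germline, chaperone and splicing factor genes were bound more often than those of other genes, and promoters of chemoreceptor, F-box and C-type lectin genes less often. The peaks marked 564 of 19973 protein-coding genes, among them 353 of 10896 named ones (3.24%). Of the 35 lists, 4 had a higher bound share and 3 a lower one by Fisher's exact test. Cytosolic ribosomal protein genes were bound at 12 of 79 (15.2%, odds ratio 5.5, Fisher's exact test, adjusted p = 9.38e-05). The strongest were rpl-15 (signal 297), rps-24 (278), rpl-35 (202) and rpl-3 (196), with summits 254 to 454 bp upstream of the 5′ end and no noncoding RNA gene within 200 bp. Germline and meiosis genes were bound at 15 of 99 (15.2%, odds ratio 5.53, Fisher's exact test, adjusted p = 1.07e-05), led by spd-5, a centrosome scaffold protein gene (signal 186, in an intron), egg-5 (149), mex-1 (124) and spd-1 (107). The egg-5 peak lay beside the SL2 RNA gene sls-2.4. Heat shock protein and chaperone genes were bound at 9 of 60 (odds ratio 5.38, Fisher's exact test, adjusted p = 0.000853), led by dnj-28 (signal 273), the chaperonin gene cct-7 (152), dnj-13 (134) and hsp-90 (120). Splicing factor genes were bound at 6 of 56 (10.7%, odds ratio 3.63, Fisher's exact test, adjusted p = 0.046). They included prp-19 through the peak it shares with K10D2.5 (signal 356), hrpr-1 (152, beside a tRNA gene), snr-2 (107.9) and uaf-1 (99.99), whose summit was 42 bp upstream.

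Of 1311 chemoreceptor genes 13 were bound (0.992%, odds ratio 0.272, Fisher's exact test, adjusted p = 1.44e-06), of 322 F-box genes 0 (adjusted p = 0.000331) and of 240 C-type lectin genes 1 (0.417%, adjusted p = 0.0303). The bound chemoreceptor genes with the highest signal were sre-23 (175, beside a snoRNA gene), srh-269 (150) and srd-44 (114.7), both beside tRNA genes, and srbc-38 (102). The bound lectin gene was clec-126 (87.2, beside 2 tRNA genes). In the lists of the single replicates, ribosomal protein genes (10 bound in replicate 2 and 11 in replicate 1) and chemoreceptor genes remained called. Germline genes (Fisher's exact test, adjusted p = 0.161 in replicate 1 and 0.552 in replicate 2), splicing factor, lectin and F-box genes did not in either list, and chaperone genes did not in replicate 2 (adjusted p = 0.584). Chaperone, splicing factor and lectin genes were not called with nearest genes only, splicing factor and lectin genes with the narrower window, splicing factor genes without tRNA gene peaks, lectin genes against all protein-coding genes, and germline, splicing factor, lectin and F-box genes at an IDR of 0.001. For germline genes the odds ratio fell to 3.27 in replicate 1, 2.93 in replicate 2 and 3.04 at an IDR of 0.001, and for chaperone genes to 3.21 in replicate 2. It stayed similar for splicing factor genes in the replicate lists (3.45 to 4.72) and without tRNA gene peaks (3.48), and for lectin genes against all protein-coding genes (0.142). F-box genes had 0 of 322 bound in replicate 2 and 1 of 322 in replicate 1 (odds ratio 0.183), and lectin genes 0 of 240 in both. For ribosomal protein genes the odds ratio was 14.5 in replicate 2 and 10.3 in replicate 1, and for chemoreceptor genes 0.126 and 0.166. With nearest genes only the odds ratio was 1.82 for chaperone and 1.44 for splicing factor genes.

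**Figure D3:**
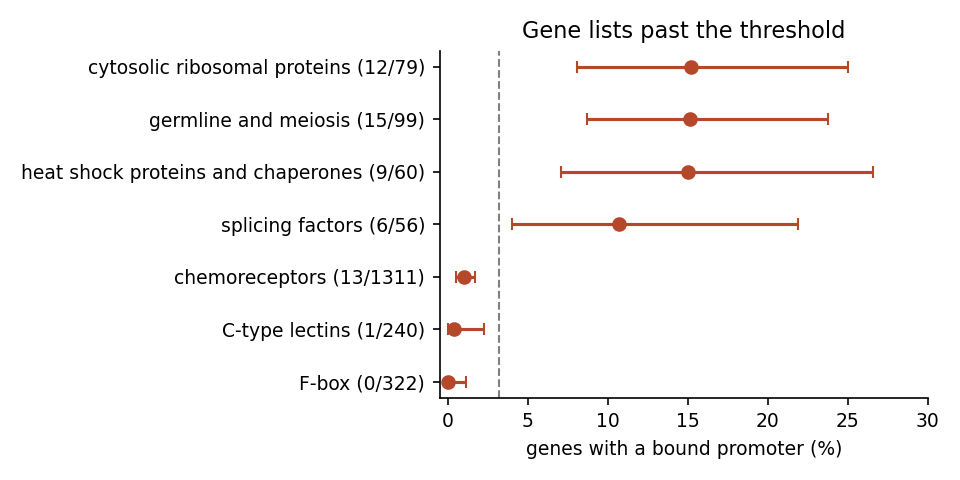
Percent of the genes of each called list with a conservative peak summit in a promoter window (points, with exact binomial 95% intervals as bars), with the bound and total members, and the share of all named genes (dashed line, 3.24%). The ribosomal protein, germline, chaperone and splicing lists lie to the right of the line and the chemoreceptor, lectin and F-box lists to the left.

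The remaining 28 lists did not pass the test, among them proteasome (0 of 33), vacuolar ATPase (0 of 20), mitochondrial ribosomal protein (2 of 66) and cytochrome P450 (4 of 190) genes. Their closest were neuropeptides and insulins (0 of 146) and chromatin regulators (8 of 101), both with a Fisher's exact adjusted p of 0.0646, and histones (6 of 72, adjusted p = 0.101). Chromatin regulators were called in 5 alternatives: IDR 0.1, the narrower window (Fisher's exact test, adjusted p = 0.0205), all protein-coding genes as background (0.0392), and the sets without tRNA (0.0331) or small noncoding RNA gene peaks (0.024). Histones, translation factors, neuropeptides and replication genes were called in the combined list, and nuclear hormone receptor genes, with a lower share, without tRNA gene peaks. Without small noncoding RNA gene peaks histones, replication and nuclear hormone receptor genes were called. At an IDR of 0.1, 8 further lists were called. The strongest bound members of these lists included nrde-2 of the small RNA pathway (signal 227), the ubiquitin conjugating gene ubc-6 (210), ears-2 among the aminoacyl-tRNA synthetases (198, summit 31 bp upstream), nhr-41 (179, beside a tRNA gene) and vps-37 (177). Next came col-85 (169), dhs-8 (167), zip-7 (164), cyp-43A1 (163), atp-5 (153), pqn-71 (145), set-2 (138.5), spp-26 (117), mrpl-23 (113) and his-47 (110). At the lower end were spe-9 (108.5), ceh-2 (98.2), pgk-1 (96.5), ric-7 (90.0), ajm-1 (87.7) and eif-3.I (79.99), and rpa-2 led the replication list. Of these, col-85, cyp-43A1, pqn-71, spp-26, spe-9, ceh-2 and ajm-1 had a tRNA gene within 200 bp of the summit, and mrpl-23 a snoRNA gene.

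In the conservative list the X chromosome held its share of the peaks by length, mostly at tRNA genes, but this share depended on the IDR limit. It had 201 of 1092 peaks, or 18.4% (95% interval 16.1 to 20.8%), against 17.7% of the nuclear length (exact binomial adjusted p = 0.526) and 13.7% of protein-coding gene starts (adjusted p = 3.71e-05). Of these X peaks, 143 (71.1%) were at tRNA genes, while on the autosomes the share was between 13.9% on II and 20.5% on IV. X carried 276 of the 612 tRNA genes. At an IDR of 0.001, added after the data were seen, X was above its length share (25%, exact binomial adjusted p = 0.00378), and at 0.1 it was below it (14.4%, adjusted p = 1.3e-09). Without the peaks at tRNA genes, an alternative chosen after the data were seen, X had 58 of 798 peaks, or 7.27% (95% interval 5.56 to 9.29%, exact binomial adjusted p = 1.21e-16 against length). Among the autosomes, I (17.8% of peaks, 15.03% of length, exact binomial adjusted p = 0.0419) and III (16.1%, 13.7%, adjusted p = 0.0499) had more peaks than their length gives, and V fewer (17.1%, 20.9%, adjusted p = 0.0119). I and III were not called in either replicate's list or at an IDR of 0.001. I was below its length share in replicate 1 (13.98%) and at that IDR (13.6%), where III was just below its own (13.6%). V was not called without the peaks at tRNA genes (19.5%) or at small noncoding RNA genes (19.9%).

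**Figure D4:**
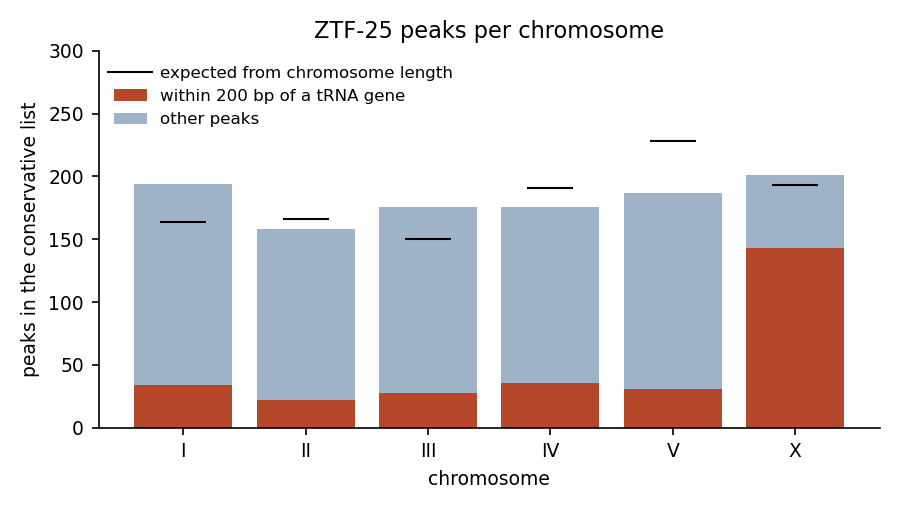
Number of conservative peaks on each nuclear chromosome, split into peaks within 200 bp of a tRNA gene (red) and other peaks (blue), with the number expected from chromosome length (black lines). X has 143 tRNA gene peaks and 58 others.

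Peaks in promoter windows were not detectably stronger than other peaks. Their median signal was 95.9 over 466 peaks, against 93.4 over the other 626, and the difference of 2.58 gave a two-sided permutation p of 0.232. Without the peaks at tRNA genes, chosen after the data were seen, the difference was 3.32 (permutation p = 0.0472).

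The word most enriched at summits was mainly found at tRNA genes. Of the 10 leading enriched words only GTGGTTA, AACCACT and TCGGCCA were also among the 10 leading words without tRNA gene peaks. The leading 7-base word, GGTTCGA, which begins the B box of the internal tRNA promoter, was in 179 of 1092 summit windows (16.4%) and 25 of 2184 control windows (1.14%), with adjusted p = 1.12e-58 by Fisher's exact test. It was in 150 of the 294 windows at tRNA genes (51.02%) and 29 of the 798 others (3.63%). Of 8192 words, 993 were more frequent at summits and 583 less frequent, and the most depleted were runs of A and T such as AAAAATT (7.97% against 20.4%). Of 319 enriched words found on chromosomes I, III and V, 308 went the same way on II, IV and X and 237 were called there again. The 612 tRNA genes have only 200 distinct sequences, so tRNA sequence by itself can repeat between chromosomes. With peaks at small noncoding RNA genes removed, 65 words were found, 62 went the same way and 40 were called again. Without the peaks at small noncoding RNA genes, chosen after the data were seen, 286 words were enriched. They were led by ATGGCCG (5.56% of windows against 0.556%) and TCGGCCA (6.4% against 0.974%), with GTGGTTA still at 3.48% against 0.139%. ATGGCCG and TCGGCCA overlap when read on opposite strands. With all peaks, TCGGCCA (7.42% against 0.824%) and GTGGTTA (8.52% against 0.458%) were also leading words. Whether these words are tRNA-like sequence was not tested, so they are not shown to be a separate preference of ZTF-25. Mean GC content was 45.1% within 100 bp of summits and 37.4% in the flanks.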

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

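The tests of gene density and of peaks left out by the authors, in the second pattern, were chosen after the results were seen, as were the values on repeats. One signal lay in data outside the main peak list. In the ranked comparison of the libraries, 61 peaks had an IDR of 0.01 or lower but were not in the conservative list, and 5 of them were stronger than any listed peak. The highest, at chromosome X, 15810950 to 15811137, had a signal of 2218 (1216 and 1196 in the single libraries), against 421.5 for the strongest listed peak. Of the 61, 55 were intergenic, 1 was in a promoter window, 0 were near a tRNA gene and 2 were near an rRNA gene. Over their length the reference marks a median of 92.8% as repeats, against 21.7% in the listed peaks (permutation p = 1e-05, the smallest possible).

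The first pattern weighed is the number of peaks at tRNA genes. Windows drawn to match the GC content of the peaks argued against GC content: over 1000 draws at most 1.28% lay near a tRNA gene, against 26.9% of the peaks. Of the 143 tRNA genes whose sequence has no exact copy, 37.1% had a peak, against 55.7% of the 469 with identical copies (Fisher's exact p = 0.000123). That p takes the copies as independent genes. A peak at a gene with no exact copy can still come from reads of a near-identical gene. It can also belong to a neighbouring gene within 200 bp, so shared reads stay open as a cause. Enrichment at any highly transcribed gene stays open. Of 27 genes known for high transcription by RNA polymerase II, 14.8% had a bound promoter (4 genes, 95% interval 4.19 to 33.7%), against 3.21% of other named genes, so part of the pattern may come from active chromatin that is recovered without ZTF-25. No biological explanation was tested, as the design has 1 group and no GFP-only sample was analysed here.

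The second pattern is the scarcity of X chromosome peaks away from tRNA genes. The X share of 7.27% was below the 13.7% of gene starts (exact binomial p = 1.63e-08), which argues against gene density. GC-matched windows fell on X at 12.9% or more in every one of the 1000 draws. The share was 6.23% in replicate 1 and 4.57% in replicate 2, so it did not rest on 1 library, and adding back the peaks the authors left out gave 7.92%. Lower transcription of X in the germline remains a candidate explanation that was not tested, and no biological explanation was tested.

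The third pattern is the bound share of ribosomal protein genes. Without peaks at tRNA, snoRNA, snRNA or rRNA genes or tRNA pseudogenes, the odds ratio was 6.25 with 11 genes bound. This argues against such genes beside the ribosomal protein genes as the source. Peaks near other annotated ncRNA genes stayed in that set, so those genes were not tested. Counting only the nearest gene of each peak left an odds ratio of 3.31 (Fisher's exact test, adjusted p = 0.0259), and GC-matched windows reached at most 10.1% of these genes over 1000 draws, against 15.2% observed. High transcription stays open here too, as these genes are highly transcribed and 14.8% of the other highly transcribed genes listed above were bound. No biological explanation was tested.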

How the results depend on the processing

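The IDR limit of 0.001 and the sets without tRNA or small noncoding RNA gene peaks were added after the data were seen. The IDR limit of 0.01 changed nothing, because the conservative list already ends there. At 0.1 only the 61 peaks known to be left out could be removed. The promoter share stayed above random in all 10 alternatives (28.0 to 54.9%, and 43.3 to 47.1% without one replicate), and the replicate overlap kept its call. The signal correlation of 0.406 over the conservative peaks is not a separate test, since these peaks were selected for ranks that repeat. In place of 1092 peaks there were 5170 at IDR 0.1, 308 at 0.001, 719 without noncoding RNA gene peaks, and 295 to 515 without one replicate. Called words, 1576 in the main set, numbered 972 as 6-mers, 666 at IDR 0.001, 2970 at 0.1, 2393 with control windows at gene starts, 665 without tRNA peaks, 431 without noncoding RNA peaks and 451 to 920 without one replicate. Called lists, 7 in the main set, numbered 3 at IDR 0.001, 15 at 0.1, 11 in the combined list, 4 with nearest genes, 11 without noncoding RNA peaks and 2 to 3 without one replicate. Called noncoding classes fell from 7 to 4 without noncoding RNA peaks, by construction. The X share was below the length share at IDR 0.1 (14.4%) and without tRNA (7.27%) or noncoding RNA peaks (7.65%), was above it and called at IDR 0.001 (25%), and 18.4% was above the gene start share. Without one replicate it was 21.36 to 22.03%, not called. The difference in signal between promoter and other peaks was -1.64 in the combined list and -1.43 to 0.105 without one replicate, none of them called. It was called at 11.1 at IDR 0.001, 3.32 without tRNA and 4.51 without noncoding RNA peaks. Smaller or larger sets change the number of tests passed by construction, and other causes were not tested. Of the 564 bound genes, 167 were also bound with the list of replicate 2 and 237 with that of replicate 1, and these sets overlap. Depth is unknown, so its limits cannot be given. No paired analysis was possible because there is only 1 group.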

Other observations

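The genes named in the next paragraph, the test of the X chromosome and the test of the B box were chosen after peaks had been seen, while the test of isotypes was chosen before its result was seen.

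Single noncoding RNA genes from the classes counted above were also looked at, with no test. The RNase P RNA gene rpr-1 had the peak ranked 9 by signal (295), with the summit 2 bp from its 5′ end. The RNase MRP RNA gene mrpr-1 (chromosome II, 7200233 to 7200418) had a peak with a signal of 121, and 2 of the 4 signal recognition particle RNA genes looked up, srpr-1.2 (87.1) and srpr-2.1 (86.5), had one. The genes srpr-1.1, srpr-2.2 and yrn-1 had none. The long noncoding RNA gene tts-1 (chromosome X, 1504131 to 1504841, minus strand) had a peak nearby (signal 107.6). Its summit lay 829 bp from the 5′ end of the gene, past the 3′ end. Among spliced leader genes, 7 of 18 SL2 RNA genes (38.9%) had a peak and 0 of 12 SL1 RNA genes did. Of the SmY RNA genes, a separate family, 1 of 12 did (smy-3, signal 93.9). How well reads map to the copies in each family was not examined, so the counts do not establish a difference between families. These SL2 RNA genes are among the 15 bound snRNA genes above, and smy-3 is among the 59 bound snoRNA genes. Outside the rule for naming, the strongest snoRNA gene peaks after ZK994.7 and T03F7.8 were at Y23H5B.10 (signal 263), F59C6.15 (258) and T19B4.8 (257).

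The bound share differed between tRNA isotypes over the 607 genes with an isotype (permutation p = 0.00727). The permutation took genes as independent, although the 612 tRNA genes have only 200 distinct sequences, so this p may be too small. It was 74.1% for aspartate (20 of 27 genes) and 71.7% for lysine (33 of 46), and 22.2% for glutamine (6 of 27). The number of identical copies of each gene was not compared between isotypes, so the mapping of reads may also have a part in this difference. On X 55.4% of tRNA genes were bound and on autosomes 47.9%, a difference that Fisher's exact test did not resolve (p = 0.0738).

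Of the 1092 peaks, 644 were not within 200 bp of any annotated noncoding gene or pseudogene other than piRNA genes. If unannotated tRNA-like genes lay there, the B box word should be more frequent at these summits. It was in 14 of 644 summit windows (2.17%) and 16 of 1288 control windows (1.24%), and Fisher's exact test gave p = 0.122, which leaves the hypothesis open. The test used 1 word, which was in only 51.02% of summit windows at tRNA genes. Another leading word of all peaks, GTGGTTA, was enriched at the 719 peaks away from small noncoding RNA genes (Fisher's exact test, adjusted p = 1.19e-07). It was not tested at the 644 peaks.

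In the conservative list 21 peaks had a pooled signal under 20, although the lowest signal of their matched peaks in a single library was 28.3.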
